A study of Mus musculus with 9 samples.

How the data were processed

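RNA was measured in 9 libraries of BV2 cells, 3 per group. Per the labels' protocols, total RNA was extracted with Trizol, and libraries were prepared with the NEBNext Ultra RNA kit for Illumina. How messenger RNA was selected and the read length are not given in the sources used here. The deposited table holds whole-number counts of reads per gene, 1 column per library, made by the authors and not normalised. Per the submitters' processing notes, the tools behind it were fastp 0.18.0, FastQC, STAR 2.7.1a and featureCounts from Subread 1.6.3, on the mouse build GRCm38. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. All 21951 gene identifiers of the table, with their symbols, were found in GENCODE M21, where each is a protein-coding gene. The 77 protein-coding genes of that release that are absent from the table all lie on unplaced or unlocalized scaffolds. Coordinates and overlaps between genes were therefore taken from GENCODE M21 on GRCm38, 1-based. Genes with a near-identical copy, such as Apol9a and Apol9b, the histone clusters, class I histocompatibility genes, Serpina families, Tuba1a and Ftl1, are uncertain as single genes, because the counting may have split or dropped their shared reads. For named genes with over 10% of their exonic bases in another gene on the same strand that share is given. Overlaps with genes of the other strand, of up to 57.2% for named genes (Fosl1), would matter as well if the counting ignored the strand.

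Groups and replicate numbers were read from the sample titles. Libraries held 13879062 to 18944051 counts. Genes with too few counts were left out by filterByExpr of edgeR with the groups, which kept 11295 genes, and 5222 of the genes left out had 0 counts in all libraries. The 3 comparisons were irradiated against control cells, triol-treated irradiated cells against irradiated cells, and triol-treated irradiated cells against control cells. Each was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation, robust dispersion and 1 fit over all 9 libraries with 6 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Adjusted p-values of single genes in the text come from this test unless another tool is named. Normalised values are CPM after TMM, and RPM is the same measure taken on a library's total count without TMM, given as mean ± SD over 3 libraries. The biological coefficient of variation was 3.18%. Log2 fold changes carry their standard error (SE) where it is given.

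Gene lists were tested with camera of limma 3.58.1 on voom values with the preset inter-gene correlation of 0.01. Adjustment was over the 31 lists with at least 5 tested members. The same test with a correlation estimated for each list is printed beside every list named as changed. For each list the number of members past the threshold is given over all tested genes and adjusted over the list alone. Counts were simulated for the comparison of triol with irradiated cells, with 200 changed genes and 11217 genes left after the filter. The test recovered 20.0% of 1.1-fold, 52.0% of 1.2-fold, 92.0% of 1.5-fold and 94.0% of 2-fold changes. False calls made up 9.15% of all its calls there. For irradiated against control cells, with 10893 genes left after the filter, the shares were 22.0%, 62.0%, 88.0% and 96.0%, and false calls made up 7.59%. The real comparisons called 12 genes for triol and 5003 for radiation. Adjusted p-values depend on how many genes change, so the shares may be too high for triol and too low for radiation. In the simulated list test, a list shifted 1.1-fold ranked 1 among 26 lists, and the number of unshifted lists that passed was 0. Its genes were drawn independently of each other, so it does not show how often lists of correlated genes pass falsely. Other splits of the real libraries, given below, called up to 16 lists. Each of them mixes libraries of both compared groups and keeps part of the real difference, so it does not show this either.

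Whether triol moved genes back was tested on the covariance across genes of the log2 fold change by radiation and the log2 fold change by triol. Both use the same irradiated libraries, which alone gives a negative value, so the covariance was set against 100 simulated draws with no effect, by the number of draws as low as the observed value. Each library was also given a position, the mean log2 CPM difference from the control mean over the genes raised, or lowered, by radiation. A control or irradiated library was scored on genes called without it. Triol-treated libraries shared the fit but not the comparison, and were scored on all called genes. In the runs that leave out a library, the genes were called without that library alone and all libraries were scored on them. Positions were compared with an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Principal components were computed on log2 CPM with a prior count of 2 over the 500 most variable tested genes.

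The groups, tests, gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. By that rule the text names, for each comparison, up to 6 genes with the largest rise and 6 with the largest fall among genes past the threshold with an average log2 CPM of at least 1 and no overlap between libraries of the compared groups. It also names 2 members per direction of each list with at least 3 members past the threshold in that direction, those with the smallest adjusted p, and a fixed set of genes chosen whatever their result. That set included Cdkn1a, Mdm2, Tnf, Il1b, Ccl2, Cxcl10, Nos2 and Abca1, and not every gene that the rule names is given in the text. Uncharacterised genes were counted but not named. For triol against control cells only the fixed set and genes named for the other comparisons are given. Genes outside the rule are marked in the text as chosen after their values were seen.

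The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper quartile scaling, no filter and a stricter filter on low counts (1 CPM in 6 libraries), a minimum log2 fold change of 1, a test against a fold of 1.2 (glmTreat), a fit of only the 2 groups compared, the replicate number as a block, the mitochondrial and the 20 most abundant genes left out, and each library left out in turn. For gene lists they also included the estimated correlation and fry. Thinning of all libraries to the smallest total, removal of trends on GC content and transcript length, leaving out triol replicates 2 and 3 together, leaving out hepatocyte genes, a simulation that keeps the radiation effect, a restriction to genes with an average log2 CPM of at least 5 and a comparison of positions on matched genes were chosen after seeing the data. Every column of the table was used.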

Results

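Gene expression was measured by RNA sequencing in BV2 cells, an immortalised line of mouse microglia, the resident macrophages of the brain. Control cells received vehicle, 20% hydroxypropyl-β-cyclodextrin, and no irradiation. Irradiated cells received vehicle for 30 min before a single X-ray dose of 10 Gy, and triol-treated cells received 10 µM triol for 30 min before the same dose. The labels name no vehicle for the triol-treated cells, so these may differ from the irradiated cells in the cyclodextrin as well, which binds cholesterol. The triol is 5α-androst-3β,5α,6β-triol, a synthetic steroid. The titles give this name for all 3 triol libraries, but the treatment labels of replicates 2 and 3 place the last hydroxyl at 7β and 8β, so the compound in those libraries rests on their titles. Triol without irradiation was not among the groups, and the time from irradiation to RNA is not given in the sources used here. Each group held 3 libraries. Total counts were 14118475 to 17705424 in control, 13879062 to 15192203 in irradiated and 17230866 to 18944051 in triol-treated libraries. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The first principal component held 77.3% of the variance and separated the control from all irradiated libraries. The third, with 4.2%, and the fourth, with 3.60%, each separated triol-treated from irradiated libraries.

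The first comparison asked how irradiation changed the transcripts of these cells. Genes induced by type I interferon and genes for replication-dependent histones rose most. Genes of antigen presentation and of mitosis rose less, and genes of the microglial state, of cholesterol and fatty acid synthesis and of the unfolded protein response fell, each as a list tested with a preset correlation. With an estimated correlation the histone list alone passed (adjusted p = 0.0055). Of 49 tested interferon-stimulated genes, 48 rose over all genes and 48 adjusted over the list alone, with a median log2 fold change of 1.55 (camera adjusted p = 4.1e-47, and adjusted p = 0.081 with an estimated correlation). Cxcl10, a chemokine that attracts T cells, on chromosome 5 from 92346638 to 92348889, rose from 4.98 ± 1.15 to 33.0 ± 3.65 CPM (mean ± SD, n = 3; log2 fold change 2.72, SE 0.11, edgeR adjusted p = 1.8e-22). Ddx58, which encodes the viral RNA sensor RIG-I, rose by 1.68 on the log2 scale (SE 0.06). The genes with the largest rise under the rule for named genes were Apol9a (5.01), Apol9b (4.32), Slfn5 (3.72), Trim69 (3.55), Ifit1bl1 (3.54) and Hist1h2bg (3.23). Apol9a and Apol9b are near-identical paralogs with 1 to 5 reads per control library, and the 95% interval for Apol9a ran from 4.37 to 5.66. Among 18 tested replication-dependent histone genes, 17 rose, also adjusted over the list alone, with a median of 2.23 (camera adjusted p = 5.8e-13, and adjusted p = 0.0055 with an estimated correlation). The linker histone genes Hist1h1c and Hist1h1d, on chromosome 13, rose by 1.36 (SE 0.05) and 3.20 (SE 0.15). These genes lie in clusters of similar sequence, and their transcripts normally lack a poly(A) tail.

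Of 27 tested genes of antigen presentation, 23 rose and 1 fell, or 23 and 2 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 2.4e-11, and adjusted p = 0.092 with an estimated correlation). The class I gene H2-Q4, a member of a multigene family, rose by 1.39 (SE 0.09), and Tap1, a peptide transporter, rose by 0.83 (SE 0.06). Of 40 tested mitotic genes, 29 rose and 2 fell, also adjusted over the list alone, with a median of 0.17 (camera adjusted p = 1.0e-07, and adjusted p = 0.35 with an estimated correlation). The mitotic cyclin gene Ccnb1 rose by 0.57 (SE 0.04) and Cdc20, an activator of the anaphase-promoting complex, by 0.38 (SE 0.04). In the NRF2 antioxidant list 19 of 33 tested genes rose and 5 fell, also adjusted over the list alone, with a median of 0.15 (camera adjusted p = 3.5e-04, and adjusted p = 0.18 with an estimated correlation). Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, rose from 118 ± 4.77 to 230 ± 8.84 CPM (log2 0.96, SE 0.04), and the cystine transporter gene Slc7a11 rose by 0.50 (SE 0.04). Nfe2l2, which encodes NRF2 itself, fell by 0.16, and the ferritin light chain gene Ftl1, which has many processed copies, fell by 0.14. Of 18 tested heat shock chaperone genes 11 rose, also adjusted over the list alone, with a median of 0.16. Among those that rose were Hsp90aa1 (0.45) and the mitochondrial chaperonin gene Hspd1 (0.34). DESeq2 and limma-voom each called 11 up and 1 down. The camera adjusted p was 5.0e-04, and adjusted p = 0.075 with an estimated correlation.

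Homeostatic microglial genes fell in 14 and rose in 2 of 25 tested members, also adjusted over the list alone, with a median of −0.29 (camera adjusted p = 7.3e-05, and adjusted p = 0.061 with an estimated correlation). Cx3cr1, the receptor for the neuronal chemokine fractalkine, on chromosome 9 from 119901616 to 120069879, fell from 32.7 ± 1.51 to 14.2 ± 0.843 CPM (log2 −1.21, SE 0.09, adjusted p = 2.5e-15). Csf1r, the receptor that microglia need for survival, fell from 519 ± 24.6 to 330 ± 0.432 CPM (log2 −0.65, SE 0.03). In the list of genes that rise in disease-associated microglia, 25 of 33 tested members fell and 5 rose, also adjusted over the list alone, with a median of −0.31 (camera adjusted p = 2.5e-10, and adjusted p = 0.15 with an estimated correlation). Here Igf1, a growth factor gene, fell by 0.93 (SE 0.04) and Cybb, which encodes the phagocyte NADPH oxidase subunit gp91phox, fell by 0.79 (SE 0.03). The phosphatidylserine receptor gene Axl rose by 1.52 (SE 0.15) and the lysosomal protease gene Ctsl by 0.42 (SE 0.03). The genes with the largest fall under the rule for named genes were Dpep2 (−1.32), the complement gene C1qc (−1.30), Cx3cr1, Maf (−1.20), the nucleotide receptor gene P2ry6 (−1.08) and the oxysterol receptor gene Gpr183 (−1.07). Of the exonic bases of Dpep2, 40.4% overlap another gene on the same strand.

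Cholesterol synthesis genes fell in 20 of 23 tested members, also adjusted over the list alone, with a median of −0.33 (camera adjusted p = 8.9e-09, and adjusted p = 0.11 with an estimated correlation). The mevalonate pathway genes Pmvk and Mvd fell by 0.76 (SE 0.06) and 0.63 (SE 0.06). Of 17 tested genes of fatty acid synthesis 11 fell and 1 rose, also adjusted over the list alone, with a median of −0.23 (camera adjusted p = 2.4e-06, and adjusted p = 0.075 with an estimated correlation). The desaturase gene Scd2 fell by 0.53 and the fatty acid synthase gene Fasn by 0.46. Genes of the unfolded protein response fell in 18 of 23 tested members, or 19 adjusted over the list alone, with a median of −0.22 (camera adjusted p = 8.9e-09, and adjusted p = 0.075 with an estimated correlation). Edem1, which acts in degradation of misfolded glycoproteins, fell by 0.52 and the transcription factor gene Xbp1 by 0.37. Abca1, the cholesterol exporter induced by oxysterols, had a log2 fold change of 0.06 (95% interval −0.01 to 0.14, adjusted p = 0.18), which passed the threshold with upper quartile scaling (adjusted p = 0.043).

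Targets of p53 did not move one way as a list. Of 35 tested members 9 rose and 10 fell, also adjusted over the list alone, with a median of 0.02 (camera adjusted p = 0.88). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 64.8 ± 1.01 to 85.6 ± 5.88 CPM (log2 0.40, SE 0.05, adjusted p = 1.2e-08). Mdm2, the ubiquitin ligase of p53, rose by 0.12 (SE 0.04, adjusted p = 0.020), a call that was lost with DESeq2 (adjusted p = 0.072) and on leaving out control replicate 2 (0.19), irradiated replicate 1 (0.15) or irradiated replicate 2 (0.089). Among inflammatory genes of the fixed set, Nos2, the inducible nitric oxide synthase, rose from 0.818 ± 0.325 to 2.84 ± 0.641 CPM (log2 1.79, SE 0.30), Tnf rose by 0.30 (SE 0.06) and Il1b by 0.72 (SE 0.21, adjusted p = 0.0051). Without control replicate 2 the value for Il1b was 0.44 (adjusted p = 0.10). Ccl2 had a log2 fold change of 0.04 (95% interval −0.10 to 0.18, adjusted p = 0.66).

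Over all 11295 tested genes, edgeR called 5003, of which 2498 rose and 2505 fell, and 5713 had an unadjusted p under 0.05. Libraries of the 2 groups did not overlap for 50.7% of tested genes, where chance gives 10%. Of the 31 lists 17 passed in camera with the preset correlation, 9 up and 8 down. With an estimated correlation 1 list stayed past the threshold, that of replication-dependent histones. With fry 18 lists passed, and 16 of the 17 kept their call and direction. The log2 change was under 0.5 for 80.3% of the called genes, and 1098 genes passed a test against a fold of 1.2, 673 up and 425 down. Of the called genes with an absolute log2 fold change of at least 1, 442 rose and 16 fell.

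**Figure D1:**
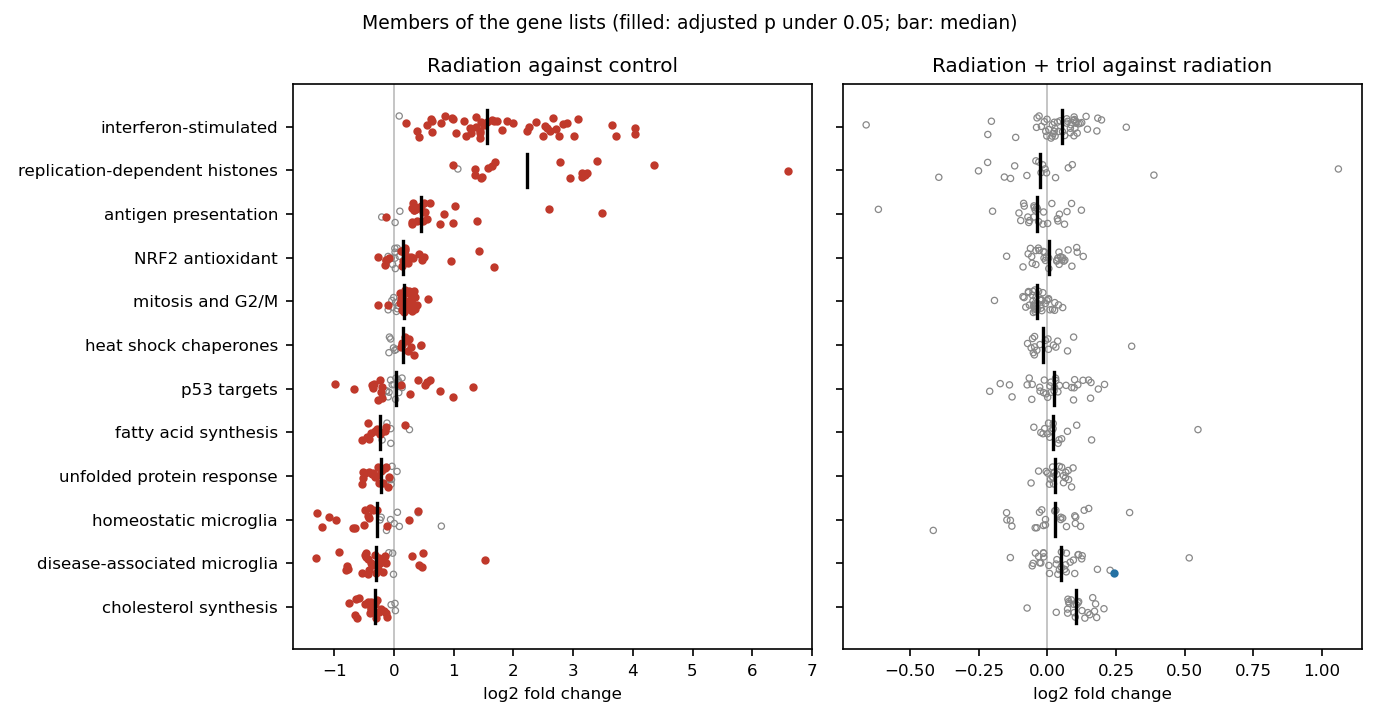
Log2 fold changes of the tested members of 12 gene lists, irradiated against control libraries on the left and triol-treated against irradiated libraries on the right, with 3 libraries per group; each point is a gene, filled where its adjusted p passed the threshold, and the bar is the list's median. On the left the interferon-stimulated genes have a median of 1.55 and the cholesterol synthesis genes a median of −0.33; on the right, on a narrower axis, the medians lie between −0.04 and 0.11.

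**Figure D2:**
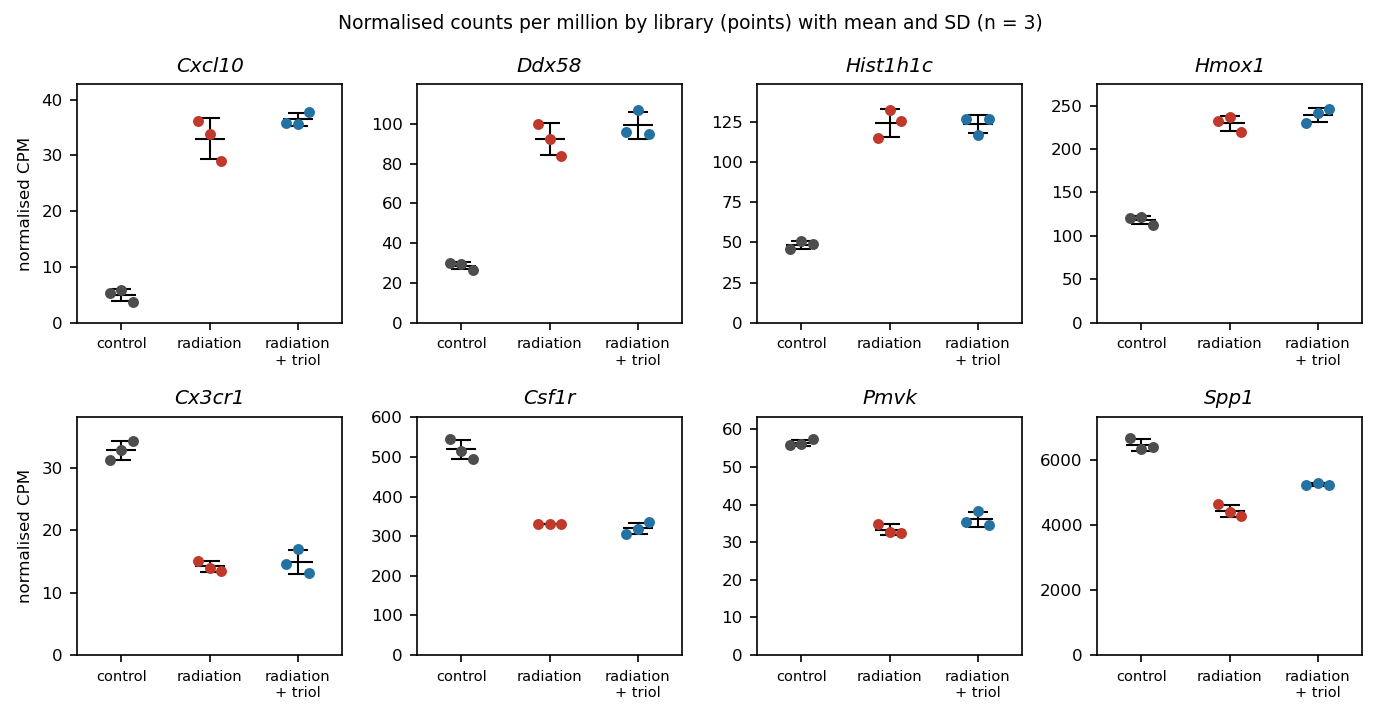
Normalised CPM of 8 genes in each library (points), with the mean and SD of 3 libraries per group, on axes that start at 0. Cxcl10, Ddx58, Hist1h1c and Hmox1 are higher and Cx3cr1, Csf1r, Pmvk and Spp1 lower in all irradiated than in all control libraries, and Spp1 is higher in the triol-treated than in the irradiated libraries.

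The second comparison asked what triol given before irradiation changed in irradiated cells. Few genes differed. Spp1, which encodes osteopontin, a secreted phosphoprotein of activated microglia, on chromosome 5 from 104435118 to 104441050, rose from 4435 ± 191 to 5253 ± 35.7 CPM (n = 3; log2 fold change 0.24, SE 0.03, edgeR adjusted p = 1.0e-06). Of its exonic bases, 18.8% overlap another gene on the same strand. Plau, which encodes the protease urokinase, on chromosome 14 from 20836660 to 20843385, rose from 288 ± 8.94 to 341 ± 19.7 CPM (log2 0.24, SE 0.04, adjusted p = 5.8e-04). Both had fallen with radiation, by 0.54 and 0.41, and both stayed lower than in control cells, with log2 differences of −0.30 and −0.17.

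Transcripts of liver genes were also higher in the triol libraries. Alb, which encodes albumin, had 61 to 82 reads per triol-treated library, 2 to 24 per irradiated library and 4 to 11 per control library, a ratio of triol-treated to irradiated RPM of 4.56 (95% exact counting interval 3.20 to 6.66, which leaves out the spread between libraries, edgeR adjusted p = 5.8e-04). Of its 37 irradiated reads 24 were in replicate 1, and the fitted log2 fold change of 2.18 became 3.09 without that library. Serpina3k and Serpina1e, protease inhibitor genes of the liver in families of close paralogs, had 19 to 37 and 14 to 24 reads per triol-treated library. In the irradiated libraries together they had 1 and 2 reads, in replicate 1 and in replicate 3, for ratios of 66.6 (interval 11.6 to 2661, adjusted p = 3.5e-05) and 23.5 (interval 6.23 to 199, adjusted p = 8.8e-04). Summed over 40 hepatocyte genes, the level was 18.2 ± 1.46 RPM in control, 24.3 ± 2.71 in irradiated and 38.4 ± 0.393 in triol-treated libraries. Without those 40 genes in the test, 5 genes passed.

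The remaining 7 calls were small, as were those of Spp1 and Plau, and each was lost on leaving out single libraries. Dmxl1, which encodes a regulator of the vacuolar proton pump, rose by 0.19 (SE 0.03, adjusted p = 0.0028) and was no longer called without irradiated replicate 1 (0.056), irradiated replicate 2 (0.061) or triol replicate 2 (0.18). The mitochondrial gene mt-Co2, which encodes a subunit of cytochrome c oxidase, fell by 0.39 (SE 0.08, adjusted p = 0.020) and was no longer called without irradiated replicate 2 (0.12), irradiated replicate 3 (0.19), triol replicate 2 (0.098) or triol replicate 3 (0.24). Emp1 (0.16), Hmga2 (0.19), the metalloprotease gene Adam8 (0.17), the tubulin gene Tuba1a (0.17, with 26.2% of its exonic bases in another gene on the same strand) and Ptchd1 (0.33) also passed, and each lost its call without at least 5 of the 6 libraries, with adjusted p of up to 0.28, 0.44, 0.41, 0.44 and 0.32. Alb, Serpina3k, Serpina1e, Emp1 and Tuba1a lie outside the rule for named genes and were chosen after their values were seen. The genes of the fixed set given here did not pass. Cxcl10 had a log2 difference of 0.15 (95% interval −0.01 to 0.30), Tnf of −0.18 (−0.29 to −0.06, adjusted p = 0.35) and Cdkn1a of 0.10 (0.00 to 0.20, adjusted p = 0.63). The values for Il1b (0.21), Ccl2 (0.17), Mdm2 (0.04), Abca1 (−0.03) and Nos2 (−0.23) had adjusted p between 0.55 and 0.91.

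In total 12 of 11295 genes passed in edgeR, 11 up and 1 down, and 865 had an unadjusted p under 0.05, where chance gives 565. Spp1, Plau, Alb, Serpina3k and Serpina1e stayed past the threshold with DESeq2, upper quartile scaling, the replicate block and each library left out in turn, wherever the tool gave an adjusted p. The number of called genes fell from 12 to 7 without any 1 of the irradiated libraries or triol replicate 1, to 6 without triol replicate 2 and to 9 without triol replicate 3. DESeq2 called 20 genes, 19 up and 1 down. The split was 15 up and 7 down with only the 2 groups fitted, and 27 up and 9 down without a filter on low counts.

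As lists, small shifts passed the test with the preset correlation only. Cholesterol synthesis genes were higher in triol-treated than in irradiated cells in 22 of 23 members, with a median of 0.11 (camera adjusted p = 1.4e-10, and adjusted p = 0.27 with an estimated correlation). For this list the number of members called was 0 with edgeR over all genes, 6 adjusted over the list alone, 8 at an unadjusted p under 0.05, 1 with DESeq2, which gave an adjusted p to 5 of the 23, and 0 with limma-voom. The 13 tested genes of the mitochondrial genome had a median of −0.12 (camera adjusted p = 2.4e-13, and adjusted p = 0.11 with an estimated correlation), with 1 called over all genes and 8 adjusted over the list alone. Ribosomal protein genes were lower in 49 of 52 members with a median of −0.05 (camera adjusted p = 5.8e-17, and adjusted p = 0.31 with an estimated correlation). Of these genes 0 were called with edgeR over all genes, 1 adjusted over the list alone, 13 at an unadjusted p under 0.05, 0 with DESeq2 (48 of the 52 with an adjusted p) and 0 with limma-voom. Disease-associated microglial genes had a median of 0.05 (camera adjusted p = 5.0e-07, and adjusted p = 0.31 with an estimated correlation). With edgeR 1 was called over all genes, Spp1, and 5 adjusted over the list alone. DESeq2 called 3, with an adjusted p for 24 of the 33, and limma-voom 2. Interferon-stimulated genes, with a median of 0.06 (camera adjusted p = 7.3e-04, and adjusted p = 0.51 with an estimated correlation), lost the call without irradiated replicate 3 (median −0.0043, adjusted p = 0.22) or triol replicate 2 (adjusted p = 0.37). None of their 49 tested members was called by edgeR over all genes or adjusted over the list alone, with 7 at an unadjusted p under 0.05, 0 by limma-voom and 0 by DESeq2, which gave an adjusted p to 7 of the 49. Secretory genes of senescence, with a median of 0.12 (camera adjusted p = 7.3e-05, and adjusted p = 0.31 with an estimated correlation), were higher in 18 of 24 members, with 1 called over all genes and 1 adjusted over the list alone. Inflammatory cytokine and chemokine genes, with a median of 0.15 (camera adjusted p = 2.2e-04, and adjusted p = 0.41 with an estimated correlation), were higher in 20 of 27. Of these edgeR called 0 over all genes, 3 up and 1 down adjusted over the list alone and 6 up and 1 down at an unadjusted p under 0.05, limma-voom 0 and DESeq2 0 of the 4 with an adjusted p. Both lists lost the call without irradiated replicate 3 (adjusted p = 0.074 and 0.15). Of 31 lists 15 passed, 9 up and 6 down; without irradiated replicate 3 it was 6 lists, of which 4 were among the 15. Those 4 were the cholesterol, mitochondrial, ribosomal and disease-associated microglial lists.

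Triol-treated irradiated cells were then compared with control cells, to see how far both treatments together lay from neither. Interferon-stimulated genes rose in 47 of 49 members, or 48 adjusted over the list alone, with a median of 1.58 (camera adjusted p = 1.4e-50, and adjusted p = 0.091 with an estimated correlation). Replication-dependent histone genes rose in 18 of 18, also adjusted over the list alone, with a median of 2.44 (camera adjusted p = 1.4e-13, and adjusted p = 0.0048 with an estimated correlation). Cholesterol synthesis genes fell in 17 of 23, also adjusted over the list alone, with a median of −0.22 (camera adjusted p = 4.3e-05, and adjusted p = 0.22 with an estimated correlation). Cxcl10 rose by 2.86 (SE 0.11), Nos2 by 1.55 (SE 0.30), Il1b by 0.92 (SE 0.20), Cdkn1a by 0.50 (SE 0.05) and Mdm2 by 0.16 (SE 0.04). Ccl2 rose by 0.21 (adjusted p = 0.016), a call lost without control replicate 2 (0.054), control replicate 3 (0.060), triol replicate 2 (0.070) or triol replicate 3 (0.061). Tnf had a log2 difference of 0.12 (adjusted p = 0.085), which passed with upper quartile scaling (adjusted p = 0.043), and Abca1 of 0.03 (adjusted p = 0.51). Inflammatory cytokine and chemokine genes rose in 13 and fell in 4 of 27, or 14 and 5 adjusted over the list alone, with a median of 0.59 (camera adjusted p = 0.016, and adjusted p = 0.68 with an estimated correlation). The mitochondrial gene list fell with a median of −0.20 (camera adjusted p = 1.3e-04, and adjusted p = 0.17 with an estimated correlation), with 8 of 13 members lower over all genes and 9 adjusted over the list alone. edgeR called 4886 genes, 2434 up and 2452 down. In camera 15 of 31 lists passed with the preset correlation and 1, the histone list, with an estimated correlation. These counts share the control libraries with the first comparison and are not independent of it.

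The last question was whether triol moved the genes changed by radiation back towards control. Of the 12 genes called between triol-treated and irradiated cells, 8 had fallen with radiation and rose with triol, where independent lists would give 2.44, and the comparisons share the irradiated libraries, which adds to such overlaps. Leaving out irradiated replicate 1, 2 or 3 gave 3, 4 and 3 such genes, where independent lists would give 1.21, 1.44 and 1.19. An expected number that allows for the shared libraries is not given. Across all 11295 genes, which are not independent replicates, the covariance of the 2 log2 fold changes was −0.00952, against −0.00840 ± 0.000355 (SD) in 100 simulated draws without effects, of which 0 were as low as the observed value. The difference, −0.00112, was −0.611% of the variance of the radiation fold changes. Without irradiated replicate 1 the difference was 0.000168, with 64 of 100 draws as low, so over all genes its sign rested on that library. Over the 6077 genes with an average log2 CPM of at least 5, a restriction chosen after seeing the data, the difference was −0.00216 (−3.98% of the variance). There it was −0.00150 without irradiated replicate 1, and 0 of 100 draws were as low in both. The SD of those draws over all libraries was 4.2e-05, far less than the range of −0.00247 to −0.00150 on leaving out irradiated libraries. The number of draws as low therefore does not measure how far a shift between libraries could move the value. Over all genes with the radiation effect kept, a simulation chosen after seeing the data, the SD of the draws was 0.000893 and the difference −0.00202. Positions of the libraries on the radiation axis put triol-treated cells close to irradiated cells. Over genes raised by radiation the irradiated libraries lay at 0.54 ± 0.03 and the triol-treated at 0.52 ± 0.01 log2 above control (mean ± SD, n = 3; exact permutation p = 0.3). Over genes lowered by radiation they lay at −0.28 ± 0.01 and −0.25 ± 0.01 (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). The irradiated libraries were scored on fewer genes than the triol-treated libraries, 2269 to 2353 against 2505 lowered genes. These permutation p-values are therefore not strictly exact. Scored on the same genes as each left-out irradiated library, a comparison chosen after seeing the data, the triol-treated mean was 96.1%, 101% and 105% of irradiated replicates 1, 2 and 3 for raised genes. For lowered genes it was 92.9%, 94.2% and 90.5%.

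**Figure D3:**
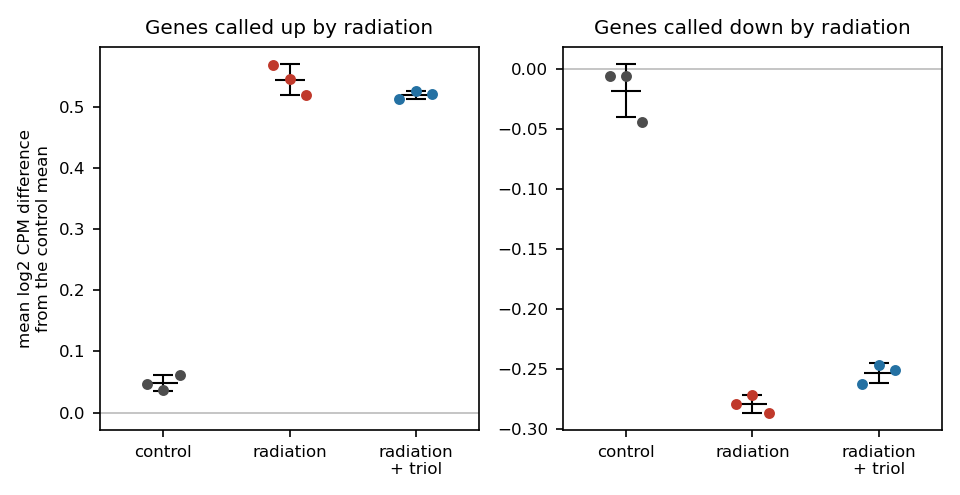
Mean log2 CPM difference from the control mean for each library (points, with group mean and SD, 3 libraries per group), over genes called up (left) and down (right) by radiation. Each control or irradiated library is scored on genes called without it. The triol-treated libraries average 0.52 and −0.25, beside 0.54 and −0.28 for irradiated libraries. Triol-treated libraries were not among the groups compared for the calls, though they shared the fit, and are scored on all called genes, a larger set.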

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

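The tests on the summed hepatocyte genes, on chemosensory receptor reads, and on the ribosomal and mitochondrial lists against control cells were chosen after the result was seen, and thinning and the removal of GC and length trends after seeing the data.

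Genes under the count minimum, which enter no comparison, drew more reads in irradiated than in control libraries: 278 ± 9.25 RPM in control, 584 ± 26.9 in irradiated and 646 ± 24.9 in triol-treated libraries (mean ± SD, n = 3), summed over 10656 genes. Genomic DNA or unspecific reads would raise silent genes alike. The 1516 olfactory, vomeronasal and taste receptor genes held 35.5 ± 2.11, 34.5 ± 3.58 and 39.6 ± 4.82 RPM. Their log2 ratio of irradiated to control was −0.0423, beside 1.07 for all genes under the minimum. That sum took in every such gene of the table, also any over the count minimum. A fall of expressed receptors could therefore hide a rise of silent ones, and the sum does not exclude such reads. Depth is argued against, because after thinning to the smallest total the lowest irradiated library still detected 918 more genes than the highest control library. Of these genes 3583 had more and 835 fewer RPM in irradiated than in control libraries, and the 100 largest gains held 15.5% of the gain, so it was spread widely. Loss of DNA methylation at germline promoters may contribute and stays open: 28 of 40 listed germline genes with reads had a median log2 fold change of 0.655, at percentile 78.2 of 10000 matched random lists, but only 4 of them reach the count minimum, so a value under the 95th percentile (1.15) does not exclude it.

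The triol-treated libraries held liver transcripts (Alb, Serpina3k, Serpina1e). Deeper sequencing of these libraries is argued against, because after thinning the lowest triol-treated library still held 63 more reads of these 3 genes than the highest other library (87 against 24). A candidate explanation is a trace of liver RNA or reads in the triol-treated libraries, since the other 37 genes of a hepatocyte list, written after the 3 calls were seen, were as a sum higher in every triol-treated library (31.6 to 32.3 RPM) than in every other library (16.0 to 24.6), a gap of 6.93. Each of the 37 was higher in the triol-treated libraries than in the other 6 together. Against the irradiated libraries alone, Rbp4 (16.4 against 16.5 RPM) and Hamp (2 against 3 reads) were not. Of the 37, Rbp4 and Ass1 are over 1 RPM in control cells. Without those 2 the sums were 10.7 to 11.8 against 1.70 to 3.66, with Mup3 and Cyp2e1 at 40 and 39 reads beside Alb at 208. Marker sums of neurons (2.10 ± 0.509 to 3.38 ± 0.411 RPM), fibroblasts (5.70 ± 0.601 to 7.31 ± 0.904) and lymphocytes (1.28 ± 0.296 to 1.92 ± 0.390) also rose from irradiated to triol-treated libraries. So did that of endothelium (325 ± 6.63 to 346 ± 11.6). That of granulocytes stayed within its spread (4.53 ± 0.660 to 4.65 ± 0.140), and those of astrocytes, oligodendrocytes and epithelium did not rise. An effect of triol on the liver genes in BV2 cells was not tested apart from such a trace and stays open, since the triol group and the liver reads coincide.

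The cholesterol, mitochondrial and ribosomal lists shifted slightly between triol-treated and irradiated libraries. Trends on GC content or transcript length are argued against as the whole cause. After removal of such trends, 3 of 3 lists kept their direction, their call and at least 89.5% of their median. The same held for 3 of 3 lists after thinning, but random removal of reads is not expected to move medians of well-counted genes. Thinning therefore cannot decide whether depth contributed. All triol-treated libraries had higher total counts than all irradiated libraries, so depth coincides with triol here and stays open. Irradiated libraries that stand apart could account for the ribosomal shift: that list gave no call between triol-treated and control cells (adjusted p = 0.905, median 0.01), but it gave one once GC and length trends were removed (median −0.12, adjusted p = 3.6e-04), so this cannot be told apart from an effect of triol. For the mitochondrial list it is argued against, because triol-treated cells also lay under control cells, with 8 of 13 members called lower by edgeR over all genes (list adjusted p = 0.000131, and adjusted p = 0.17 with an estimated correlation). By library, the mean log2 distance from control was −0.14, −0.05 and 0.02 in irradiated and −0.13, −0.21 and −0.28 in triol-treated replicates for the mitochondrial list, and −0.32, −0.35 and −0.35 against −0.24, −0.17 and −0.29 for the cholesterol list, where an effect of triol, or of a vehicle that the labels do not name for the triol-treated cells, stays open and the call rests on the preset correlation.

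With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Every other split mixes libraries of both groups. It therefore keeps part of the real difference, and it widens the spread within each side, which lowers the number of genes called. For genes of the radiation comparison, fitted on its 6 libraries, the real split called 4770 and the highest other 0 (edgeR), so 1 of 10 splits gave as many. For triol against irradiated cells it was 22 against 2, also 1 of 10, and for triol against control cells 4848 against 0, also 1 of 10. For gene lists the real split called 17 and the highest other 16 in the radiation comparison (1 of 10). In the triol comparison it was 15 against 16 (2 of 10), where irradiated replicates 1 and 3 with triol replicate 1 formed the other side, and in triol against control cells 15 against 15 (2 of 10).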

How the results depend on the processing

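Thinning, removal of GC and length trends, the runs without triol replicates 2 and 3 or without hepatocyte genes, the restriction to genes of average log2 CPM of at least 5, the matched positions and the simulation that keeps the radiation effect were chosen after seeing the data. Without triol replicates 2 and 3 the lone triol library is assumed to vary like the other groups. Where no cause is given, the cause was not tested. Counts for radiation stayed within 4215 and 5165 of the main 5003 except with tests that ask for a minimum change, glmTreat (1098, 673 up and 425 down) and an absolute log2 fold change of at least 1 (458, 442 up and 16 down); leaving out single libraries gave 4266 to 4841. For triol against control these were 1040 and 487. The 12 triol calls became 20 with DESeq2, 36 without a filter (27 up and 9 down), 5 with the stricter filter, 3 with glmTreat, 3 with the log2 minimum, 22 with only the 2 groups (15 up and 7 down), 7 after thinning, 5 without triol replicates 2 and 3, 5 without hepatocyte genes, and 6 to 9 on leaving out single libraries. DESeq2 gave no adjusted p to 5 of the 12 genes and shared the other 7. The replicate block gave 22 (17 up and 5 down), of which 12 were shared, and left the counts of the other 2 comparisons and all list counts within 1.5 times. Replicate numbers do not pair the libraries: same-numbered libraries correlated at −0.052 to 0.044 after removing group means, and 4 of 9 correlated best with their own number. Lists called went from 17 to 1 for radiation, 15 to 0 for triol and 15 to 1 for triol against control with an estimated correlation; the triol lists went to 0 with fry, to 8 without triol replicates 2 and 3 and to 6 to 18 on leaving out single libraries. With the estimated correlation the smallest adjusted p of the triol lists was 0.107, 3 lists had an unadjusted p under 0.05, and with fry these were 0.227 and 5. The other 2 comparisons held with fry. It called 18 lists for radiation, with 16 of the 17 kept, and 17 for triol against control, with 15 of the 15 kept. The reversal covariance difference was −0.00329 to 0.000168 on leaving out irradiated libraries, the positive value without replicate 1; over the restricted genes it was −0.00216 (−0.00247 to −0.00150 on leaving out irradiated libraries), with the radiation effect kept −0.00202, and with the block −0.00112, unchanged, since the block is balanced. Genes called in opposite directions went from 8 to 19 with DESeq2, 15 with the block, 4 with upper quartile scaling and 3 to 4 on leaving out irradiated libraries. The DESeq2 count was taken over 2374 genes, where independent lists would give 6.55 genes lowered and then raised. In the main setting this was 2.44 over 11295 genes. On the radiation axis, the triol minus irradiated difference for raised genes went from −0.024 to 0.0154 for genes of log2 of at least 1 and to 0.00292 on matched genes, and lay at −0.0385 with DESeq2 and −0.0447 with the block (exact permutation p = 0.1 each, the smallest possible, against 0.3). For lowered genes it went from 0.026 to 0.0356 with DESeq2, 0.0626 with the log2 minimum and 0.0348 to 0.0375 on leaving out single libraries, and lay at 0.0209 on matched genes. The runs without single libraries scored irradiated libraries on genes that they helped to call, so they do not bear on the stability of the difference; for raised genes they gave −0.0262 to −0.0223. Of lists called in at least 1 of the 2 settings compared, the test turned in direction for the ribosomal list for radiation without GC and length trends (−0.0662), the ribosomal list for triol against control likewise (−0.119), the interferon list for triol without irradiated replicate 3 (−0.0043 to 0.13 over single libraries left out) and oxidative phosphorylation for triol without replicates 2 and 3, whose median stayed negative (−0.00120). Upper quartile scaling split the radiation calls 2919 up and 2116 down. As to depth, the simulated triol comparison recovered 20.0% of 1.1-fold and 52.0% of 1.2-fold changes over all genes, and 38.5% and 86.4% above 32 CPM.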

Other observations

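A set of 6 further lists passed for irradiated against control cells with the preset correlation, and none of them with an estimated correlation. Ribosomal protein genes rose in 17 and fell in 3 of 52 tested members, also adjusted over the list alone, with a median log2 fold change of 0.06 (camera adjusted p = 0.0054, and adjusted p = 0.69 with an estimated correlation); Rplp1 (0.17) and Rps19 (0.17) rose, Rpl3 (−0.17) and Rpsa (−0.09) fell, and the call was lost without control replicate 3 (adjusted p = 0.059) and with fry (0.10). With GC and length trends removed, which was chosen after seeing the data, the median turned to −0.07 (adjusted p = 0.19). Targets of the oxysterol receptor LXR fell in 10 and rose in 2 of 19, also adjusted over the list alone, with a median of −0.13 (camera adjusted p = 0.0066, and adjusted p = 0.26 with an estimated correlation), among them the lipoprotein lipase gene Lpl (−0.43). Genes of cytosolic nucleic acid sensing rose in 7 and fell in 2 of 16, also adjusted over the list alone, with a median of 0.06 (camera adjusted p = 0.0073, and adjusted p = 0.36 with an estimated correlation), among them Ifi204 (1.29). Genes of lysosomes and autophagy fell in 18 and rose in 5 of 34, also adjusted over the list alone, with a median of −0.11 (camera adjusted p = 0.0073, and adjusted p = 0.51 with an estimated correlation); the hydrolase gene Gusb (−0.31) fell and the autophagy receptor gene Sqstm1 (0.16) rose. Genes of double-strand break repair rose in 11 and fell in 1 of 38, or 9 and 1 adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.026, and adjusted p = 0.51 with an estimated correlation). Of these Xrcc5, which encodes Ku80, rose by 0.56 and the exonuclease gene Exo1 by 0.55, and the list lost its call without control replicate 1 (adjusted p = 0.092) or irradiated replicate 3 (0.091). Genes of phagocytosis and complement fell in 16 and rose in 6 of 30, or 16 and 9 adjusted over the list alone, with a median of −0.21 (camera adjusted p = 0.045, and adjusted p = 0.51 with an estimated correlation). Here Itgb2 (−0.46) and Tyrobp (−0.48) fell and the complement gene C3 (1.11) and the scavenger receptor gene Cd36 (0.43) rose, and the call was lost without control replicate 1 (adjusted p = 0.070), control replicate 2 (0.055) or irradiated replicate 3 (0.091), with only the 2 groups (0.054), after thinning (0.055) and with GC and length trends removed (0.070).

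Other lists had members that changed under radiation without a call of the list, in both directions except for the mitochondrial genome. Genes of DNA replication rose in 12 and fell in 4 of 45 (camera adjusted p = 0.055), which passed without control replicate 3 (0.020) or irradiated replicate 1 (0.032), with fry (0.034), upper quartile scaling (0.030) and only the 2 groups (0.049), while its median turned to −0.04 with GC and length trends removed (adjusted p = 0.22); Mcm10 (0.71) rose, and Rfc2 (−0.46) and Tk1 (−0.35) fell. Inflammatory cytokine and chemokine genes rose in 13 and fell in 8 of 27 with a median of 0.40 (camera adjusted p = 0.20), with Ccl9 (1.32) up and Ccl7 (−0.77) and Tnfsf9 (−0.41) down. Of 24 secretory genes of senescence 8 rose and 7 fell (camera adjusted p = 0.88), with Ccl5 (2.03) up and the urokinase receptor gene Plaur (−0.24) down. Of 30 genes of the apoptosis list 9 rose and 5 fell (camera adjusted p = 0.88): the pro-apoptotic Bcl2l11 (0.32) and Pmaip1 (0.27) rose and the anti-apoptotic Bcl2 (−0.73) and Bcl2l1 (−0.35) fell. Of the p53 list Cd80, which encodes a costimulatory ligand, rose by 0.98, and Apaf1 (−0.24) and Sesn1 (−0.36) fell. In the NF-kB list 7 rose and 8 fell of 28 (camera adjusted p = 0.95), with Traf1 (1.12) and Icam1 (0.54) up and Tnfaip3 (−0.40) and Tnfaip2 (−0.26) down. In the immediate early list 5 rose and 11 fell of 27 (camera adjusted p = 0.52), with Fosl1 (1.03) and Dusp5 (0.51) up and Fos (−0.56) and Jun (−0.23) down. For the lists of pyroptosis (6 up, 4 down; Casp4 0.92, Gsdmd −0.24), glycolysis (3 up, 7 down; Slc16a1 0.61, Aldoc −0.50), hypoxia (4 up, 7 down; P4ha1 0.13, Egln1 −0.30), ATF4 targets (8 up, 11 down; Slc3a2 0.34, Mars −0.24), oxidative phosphorylation (3 up, 7 down; Cox5a 0.18, Sdhc −0.30) and the mitochondrial genome (0 up, 3 down; mt-Cytb −0.14), the camera adjusted p was 0.59, 0.13, 0.66, 0.81, 0.52 and 0.26. With GC and length trends removed, 3 of these lists passed: the mitochondrial genome (median −0.25 instead of −0.05, adjusted p = 0.0068), oxidative phosphorylation (−0.15 instead of −0.03, adjusted p = 0.0068) and glycolysis (−0.13 instead of −0.05, adjusted p = 0.043), and glycolysis also passed with fry (0.013).

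A further 8 lists passed for triol-treated against irradiated cells with the preset correlation only, with small medians. Those were mitosis (−0.04), lysosomes and autophagy (0.03), DNA replication (−0.02), the unfolded protein response (0.03), ATF4 targets (0.05), hypoxia (0.04), double-strand break repair (−0.04) and oxidative phosphorylation (−0.02). Their camera adjusted p was 5.5e-04, 0.0026, 0.0029, 0.0029, 0.015, 0.028, 0.029 and 0.039. For the unfolded protein response, ATF4 and hypoxia lists adjusted p = 0.31 with an estimated correlation, and for the other 5 adjusted p = 0.41 with an estimated correlation. Without irradiated replicate 3 all 8 lost their call, with adjusted p of 0.050 to 0.36. Calls were also lost without irradiated replicate 1 (hypoxia 0.085), irradiated replicate 2 (oxidative phosphorylation 0.15) and triol replicate 1 (ATF4 0.091). Without triol replicate 2 this held for DNA replication (0.075), the unfolded protein response (0.053), hypoxia (0.053), repair (0.070) and oxidative phosphorylation (0.070), and without triol replicate 3 for lysosomes (0.061), hypoxia (0.056), repair (0.075) and oxidative phosphorylation (0.32).

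Ifnb1, which encodes interferon beta and lies under the count minimum of the test, had 0 reads in every control library, 4 to 7 in each irradiated library (17 in total) and 6 to 7 in each triol-treated library (20 in total), and was chosen after its values were seen. Cell type markers were summed over lists, in RPM, with levels given for control, irradiated and triol-treated libraries (n = 3 each). They were 0.512, 2.10 and 3.38 for neurons, 2.93, 5.70 and 7.31 for fibroblasts and 1.04, 4.53 and 4.65 for granulocytes. For astrocytes they were 262, 244 and 238, for endothelium 389, 325 and 346, and for oligodendrocytes 37.6, 43.5 and 42.8. Markers of epithelium were at 5.86, 4.52 and 4.29 and those of lymphocytes at 1.05, 1.28 and 1.92.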
